A study of Mus musculus with 2 samples.

How the data were processed

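Total RNA of mouse embryonic fibroblasts was taken with TRIzol after cells were loaded with calcein and cobalt chloride and sorted by calcein fluorescence, and libraries were made with an Illumina TruSeq kit, per the labels' protocols. The 2 libraries, 1 of the high and 1 of the low mPTP opening pool, were matched to their columns by name. The authors deposited 1 table of FPKM values with Ensembl gene identifiers, names, biotypes and positions. TopHat2 2.0.12, Bowtie2 2.2.3 and the genome build mm10 are named in the submitters' processing notes. The counting tool, the annotation and whether counting used strand are not given in the sources used here. Overlapping genes on opposite strands and close paralogs may therefore share reads. Genes at 0 in both libraries are not listed in the table.

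The deposited FPKM values times the exon length of each gene in the GENCODE M21 annotation were whole multiples of 1 step per library. Of the genes with up to 20 reads, 93.2% in the low and 93.5% in the high mPTP opening library came out whole within 0.05 reads (85.7% and 85.6% of all genes). The steps gave denominators of 15060426 and 16375720 reads or fragments. For a gene of 1 kilobase, 1 FPKM is then 15.1 and 16.4 reads, and 3 reads are 0.199 and 0.183 FPKM. The reads recovered over all genes were 1.10 times the denominator in both libraries. Reads were used for exact Clopper-Pearson intervals of the ratio of 2 libraries, given the sum of their reads, at 95%. They also set the levels in the simulations of counting error and of test data. Genes whose FPKM did not come out whole, such as Myh11, Kif20a, Clu and Cdkn1a, had their reads rounded, so their intervals are approximate. PCR copies are not independent molecules, and the intervals cover counting error only. Of the gene identifiers, 99.7% were found in GENCODE M21, and 86.7% had the same position there; positions in the text are those of the deposited table.

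Differences were computed as log2((high + 1)/(low + 1)) of FPKM, a scale that understates differences of low genes, while ratios in the text are of FPKM itself. Rows of 1 symbol were added, which left 23084 symbols. Genes with a mean of at least 1 FPKM were the measured genes. With 1 library per group no p-value was computed and genes were ranked by size, with 2-fold as the size rule. Counting error was simulated by drawing the reads of both libraries from common levels 20 times.

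Gene lists (37) and cell type marker lists (16) were fixed before the data were examined. A list member counted as higher or lower at 1.5-fold or more on the log2(FPKM + 1) scale. Each list with at least 5 measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, and stood apart with a median below percentile 2.5 or above percentile 97.5. The rule for named genes, also fixed before, took the 12 largest differences in each direction past the size rule with a mean of at least 5 FPKM, without clone, predicted, small RNA or pseudogene names (4 higher genes met it). It also took up to 4 members of each list with the largest differences, measured members of the pore, dye handling, demethylase and pluripotency lists, any cell type marker, and the 3 genes with the highest FPKM in each library. Myc is named as a member of the pluripotency list.

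The alternatives were pseudocounts of 0.1 and 5 FPKM, scaling by the median ratio, by a trimmed mean of log ratios or to a sum of 1000000 with and without mitochondrially encoded genes, other filters on the mean, sizes of 1.5-fold and 4-fold, leaving out predicted names, the highest row of each symbol, unmatched random lists and each list without its furthest member. Random lists matched also on exon length, and counts without genes under 600 nt of exon, were added after seeing the data. The scripts were tested on simulated data for 23019 genes of this comparison. Genes simulated with a 1.5 or larger log2 increase all passed the size rule, as did 92% of those with a decrease of 1.5 and all with the larger decrease. Of 11662 unchanged measured genes 40 passed it, 1 of 40 unchanged lists fell outside the limits, and 95% of counting intervals held the true ratio. The simulation held counting error alone, with each gene drawn independently. It therefore tests the scripts, and not variation between cultures or sorts or genes that vary together. Its changed genes and its lists were drawn from genes above the cutoff of the measured genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.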

Results

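RNA was sequenced from mouse embryonic fibroblasts of the ICR strain, which are primary cells grown from embryos, after a sort by opening of the mitochondrial permeability transition pore (mPTP). The mPTP is a large channel of the inner mitochondrial membrane. In the calcein assay the dye loads the whole cell and cobalt quenches it outside closed mitochondria, so bright cells are those with little pore opening. The bright pool was the low mPTP opening group and the dim pool was the high mPTP opening group. Each group had 1 library, so no difference reported here has a replicate check, and the values describe these 2 libraries only. The deposited table holds FPKM (fragments or reads per kilobase of gene, scaled by library depth) for 23097 genes. The size of its steps gave a depth of 15060426 reads or fragments for the low mPTP opening library and 16375720 for the high mPTP opening library. Intervals after a ratio are exact 95% intervals for counting error alone, which leave out variation between cultures and sorts.

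The comparison asked how transcript levels differed between cells with high and low mPTP opening. As lists, genes of cholesterol and fatty acid synthesis, of cell division and of the contractile actin cytoskeleton had higher medians in the high mPTP opening library. Macrophage markers, p53 targets, immediate early genes, interferon-stimulated genes and lysosomal genes had lower medians. Of 28 measured genes of cholesterol and fatty acid synthesis 13 were 1.5-fold or more higher, with a median log2 difference of 0.57, and 13 of 16 measured macrophage markers were 1.5-fold or more lower, with a median of -0.94. Genes of the pore and its regulators lay close together in the 2 libraries, with 0 of 28 differing by 1.5-fold or more and a median of 0.07. This is not particular to the pore, since of all 11898 measured genes 183 were higher and 521 lower by that size.

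The genes with the largest differences at a mean of at least 5 FPKM belonged to several of these groups. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194527 to 14291408), was 3.06-fold higher in the high mPTP opening library (95% interval 2.70 to 3.47), at 8.78 against 2.86 FPKM. Actg2, the enteric smooth muscle actin (chromosome 6, 83512905 to 83536265), was 2.19-fold higher (2.05 to 2.34), at 117 against 53.3 FPKM. Pax1, a transcription factor of the sclerotome, was 2.40-fold higher (2.08 to 2.78), and Kif20a, a kinesin of cytokinesis, was 2.12-fold higher (1.95 to 2.30), although 29.3% of Kif20a exon sequence is shared with an overlapping gene. Apoe, an apolipoprotein made in quantity by macrophages (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was 3.12-fold lower in the high mPTP opening library (2.96 to 3.30), at 50.7 against 158 FPKM. Clu, a secreted chaperone (chromosome 14, 65968483 to 65981548), was 3.36-fold lower (2.96 to 3.83). Mmp13, a collagenase (chromosome 9, 7272514 to 7283331), was 3.05-fold lower (2.80 to 3.32), and Ctsf, a lysosomal cysteine protease, was 2.89-fold lower (2.62 to 3.18). The other lower genes at the top of the ranking were Upk3b and Upk1b, which are mesothelial markers, the chemokines Ccl3, Ccl12 and Pf4, and the leukocyte genes Pld4, Lst1 and Lyz2. Their ratios of low to high lay between 2.21-fold for Lyz2 and 2.87-fold for Ccl3. Actg2 and Lyz2 have close paralogs that can share reads, so their values are uncertain to that extent.

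Of the 11898 measured genes, with a mean of at least 1 FPKM, 39 were 2-fold or more higher in the high mPTP opening library and 114 were 2-fold or more lower on the log2(FPKM + 1) scale. Redrawing the reads of both libraries from common levels, 20 times, gave up to 36 higher and 30 lower genes, so the 39 higher genes barely exceed what counting error alone can give. With a mean of at least 5 FPKM, 8 genes were higher and 32 lower, against at most 4 and 3 from counting error. At 1.5-fold or more, 183 genes were higher and 521 lower, against at most 71 and 79. Predicted and small RNA names made up 28 of the 39 higher and 54 of the 114 lower genes. The share of higher genes among those past 2-fold was 25.5% with FPKM as deposited, and 41.1% (269 higher, 385 lower) after each library was scaled to a sum of 1000000, which raises every ratio by 0.12 on the log2 scale. A single row, Gm23935 with 57 nt of exon, held 12.6% of the low and 5.89% of the high FPKM sum, which bears on this shift. Scaling by the median ratio shifted ratios by -0.0018 and scaling by the trimmed mean by 0.081. Across genes, which are not independent replicates, log2 FPKM of the libraries had a Pearson correlation of 0.981 and a Spearman correlation of 0.978.

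**Figure D1:**
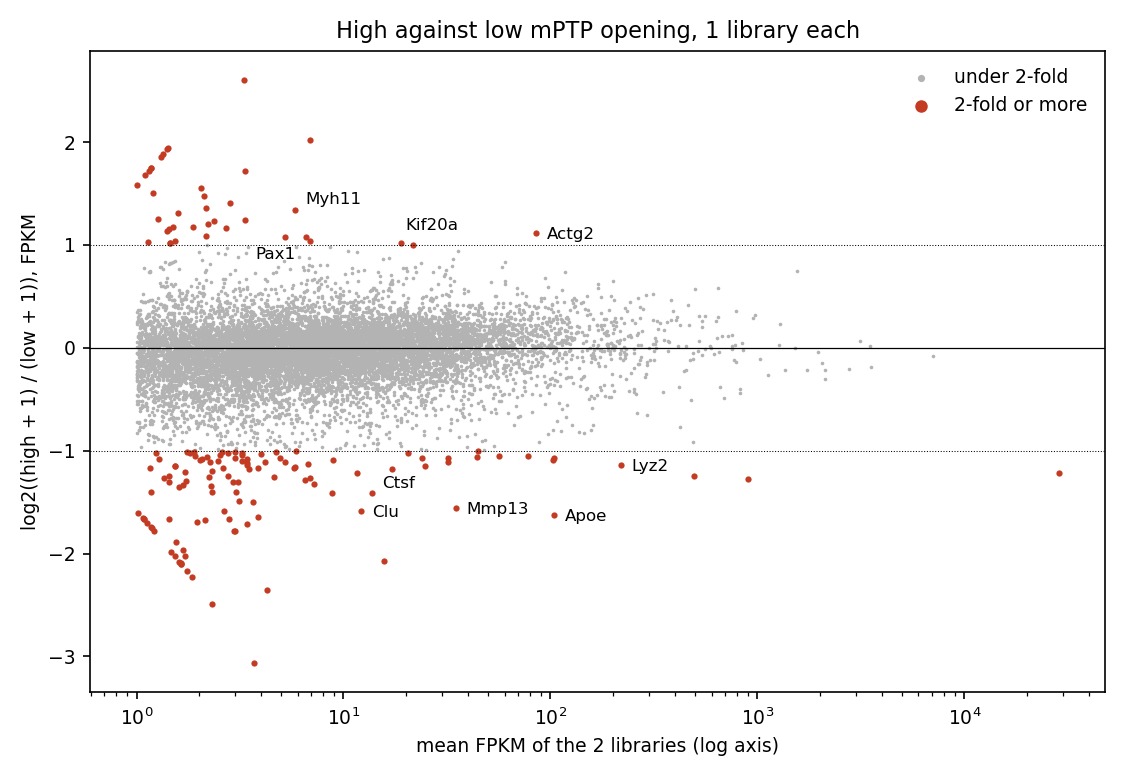
Each point is 1 of 11898 measured genes, with the mean FPKM of the 2 libraries on a log axis and log2((high + 1)/(low + 1)) on the vertical axis, and red points lie 2-fold or more from 0 (dotted lines). Most red points sit at low FPKM, while Apoe, Mmp13 and Lyz2 stand below -1 and Actg2 above 1 at higher FPKM.

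Cholesterol and fatty acid synthesis was the gene list with the highest median. All 28 measured members had a positive difference, and those short of 1.5-fold numbered 15. Idi1, which isomerises isopentenyl diphosphate, was at 44.0 against 23.7 FPKM, a ratio of 1.85 (1.73 to 1.99). Scd1, the stearoyl-CoA desaturase, was at 77.7 against 43.2 FPKM, a ratio of 1.80 (1.72 to 1.88). Cyp51, the lanosterol demethylase, had a ratio of 1.74 (1.67 to 1.83). The list median lay at percentile 100 of the medians of 10000 random lists matched on mean expression, which describes these libraries and is no test between conditions.

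The median of cell cycle genes was higher in the high mPTP opening library in both phases examined. Of 55 G2 and M phase genes 52 had a positive difference and 20 were 1.5-fold or more higher, with a median of 0.50 (percentile 100). Cdc20, an activator of the anaphase-promoting complex, was at 47.2 against 24.1 FPKM, with an interval of the ratio from 1.79 to 2.15. Tpx2, a spindle assembly factor, had a ratio of 1.81 (1.69 to 1.95), and Cenpe, a kinetochore kinesin, had a ratio of 1.88 (1.72 to 2.06). All 43 measured S phase genes had a positive difference, with a median of 0.31 (percentile 100), but 1 of them reached 1.5-fold. This was Rrm2, a ribonucleotide reductase subunit, at 42.1 against 26.4 FPKM. Genes of ribosome biogenesis and Myc targets had a median of 0.24 (percentile 100, 23 of 24 positive, 0 by 1.5-fold), with Cad, the enzyme that starts pyrimidine synthesis, at 17.1 against 11.7 FPKM. Myc itself was at 14.1 against 18.5 FPKM.

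The p53 targets showed the opposite direction. Of 27 measured targets 24 had a negative difference, 5 of them by 1.5-fold or more, with a median of -0.29 (percentile 0). Cdkn1a, the cyclin-dependent kinase inhibitor p21, was at 50.4 against 106 FPKM, 2.09-fold lower. Pmaip1, a pro-apoptotic BH3-only gene, was 2.29-fold lower (1.89 to 2.78), and Trp53inp1 was 2.06-fold lower (1.94 to 2.18). Senescence and secretory factors had a median of -0.31 (percentile 0), with 7 of 17 members lower by 1.5-fold or more and 1 higher. A link to the macrophage markers, with a median of -0.94, was not tested. Mmp13, Cdkn1a, the neutrophil chemokine Cxcl2, at 1.36 against 4.82 FPKM, and Igfbp5, at 338 against 640 FPKM, led the senescence list. Apoptosis regulators as a list did not stand apart, with 3 of 27 lower by 1.5-fold or more and a median of -0.01, which turned positive after scaling by the trimmed mean or to a common sum.

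The median of contractile genes was higher in the high mPTP opening library. Of 23 actin and serum response factor targets 22 had a positive difference, 5 of them by 1.5-fold or more, with a median of 0.44 (percentile 100). Acta2, the smooth muscle alpha actin, was at 1953 against 1166 FPKM, a ratio of 1.67 (1.65 to 1.70), and Cnn1, a calponin, had a ratio of 1.76 (1.59 to 1.94). Ankrd1, a target of YAP signalling, had a ratio of 2.06 (1.72 to 2.48). Acta2 and Actg2 are paralogs, and the counting behind the table could divide reads between them. Smooth muscle and pericyte markers had a median of 0.18 (percentile 99.6), with 4 of 12 higher by 1.5-fold or more, and those 4 (Myh11, Actg2, Cnn1 and Acta2) are also in the actin list. The other 8 lay between, and of these Lmod1 and Tagln are in the actin list too. Outside the actin list, Cspg4 and Mcam had a positive difference, while Abcc9, Notch3, Kcnj8 and Rgs5 were the 4 markers with a negative one. The list median thus leans on genes shared with the actin list. The pericyte channel gene Abcc9 was at 1.01 against 1.97 FPKM, and Notch3 had a ratio of 0.659 (0.607 to 0.715).

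Markers of several other cell types were lower in the high mPTP opening library. Of 16 macrophage markers 13 were lower by 1.5-fold or more and 3 lay between (percentile 0). C1qa, a complement C1q chain, was at 66.7 against 141 FPKM, 2.12-fold lower (1.97 to 2.28), Tyrobp, a myeloid signalling adaptor, was 2.21-fold lower (1.87 to 2.61), and Cd68 was at 35.9 against 70.5 FPKM. Glia and Schwann markers had a median of -1.30 (percentile 0, 5 of 5 lower), which was -2.13 with a pseudocount of 0.1 FPKM and -0.50 with 5 FPKM. Sox10, the neural crest transcription factor, was at 0.0900 against 3.26 FPKM, 36.2-fold lower (15.6 to 152), and Cdh19 was 47.2-fold lower (19.9 to 147). Mesothelial markers had a median of -0.75 (percentile 0, 6 of 7 lower by 1.5-fold or more), with Msln at 3.81 against 8.35 FPKM. Fibroblast markers had a median of -0.05 (percentile 13.7), a sign that turned positive after scaling by a trimmed mean of log ratios or to a sum of 1000000, with Dcn at 98.9 against 175 FPKM and Thy1 at 81.7 against 56.6 FPKM. Chondrocyte markers had a median of 0.20 (percentile 99.1, 6 of 7 positive), which did not stand apart after scaling to a sum of 1000000 or with another filter on low FPKM, and osteoblast markers, with a median of -0.07, did not stand apart. The remaining marker lists had under 5 measured members and got no percentile. Their medians were -0.83 for 4 keratinocyte and epithelial genes, -0.74 for 4 adipocyte genes, -0.66 for 2 cardiac muscle genes, -0.53 for 4 skeletal muscle genes, -0.04 for 3 neuronal genes and -0.03 for 3 endothelial genes. The osteoblast, neuronal and endothelial medians turned positive after scaling by the trimmed mean, and the skeletal muscle median was 0.39 at a mean of at least 5 FPKM. None of the erythroid, hepatocyte or germ cell markers reached a mean of 1 FPKM.

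**Figure D2:**
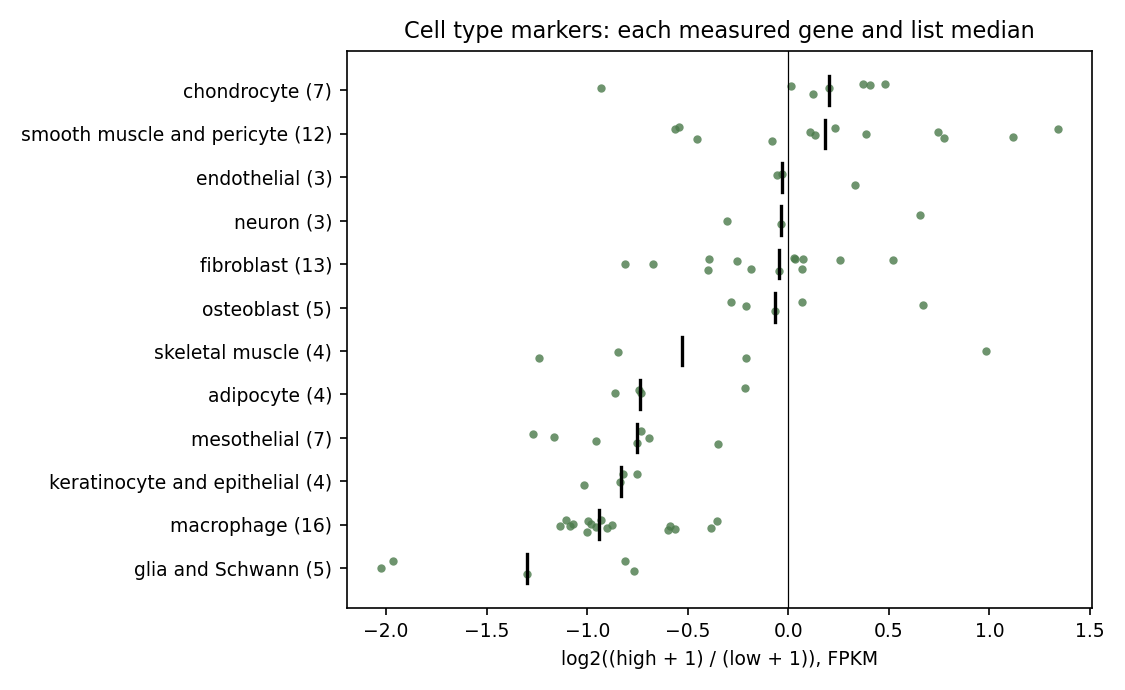
Each point is a measured marker gene (number in brackets), its position along the horizontal axis is log2((high + 1)/(low + 1)) of FPKM, and the black bar is the list median; vertical scatter within a list has no meaning. All macrophage, mesothelial and glial points lie left of 0, with medians of -0.94, -0.75 and -1.30.

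Lysosomal, interferon and immediate early genes had lower medians in the high mPTP opening library. Macrophage markers were lower there too, with a median of -0.94, and whether this bears on these lists was not tested. Lysosome and autophagy genes had a median of -0.32 (percentile 0, 30 of 31 negative, 2 by 1.5-fold or more), with Ctsd, the aspartic protease cathepsin D, at 115 against 200 FPKM, 1.74-fold lower (1.68 to 1.81). Interferon-stimulated genes had a median of -0.41 (percentile 0, 23 of 23 negative, 2 by 1.5-fold or more), with Ifit1 at 3.61 against 6.65 FPKM. Immediate early genes had a median of -0.41 (percentile 0, 28 of 28 negative, 6 by 1.5-fold or more), with Atf3 at 15.5 against 27.2 FPKM and Nr4a1 at 49.6 against 84.1 FPKM. Inflammatory and NF-kB targets had a median of -0.12 (percentile 7.21) and did not stand apart, a call that changed in 3 of 12 alternatives, and the median turned to 0.0068 at a mean of at least 5 FPKM, although Cxcl2 and Tnf, at 0.931 against 3.12 FPKM, were lower.

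Genes of the pore machinery differed little. Ppif, which encodes cyclophilin D, the regulator of the pore, was at 3.14 against 2.64 FPKM, a ratio of 1.19 (0.982 to 1.43), so a difference was not detectable at this depth. The adenine nucleotide translocators Slc25a4 and Slc25a5 had ratios of 0.987 and 1.13, and the outer membrane channel Vdac1 had a ratio of 1.06. The members furthest apart on the log2(FPKM + 1) scale were Atp5b, the ATP synthase beta subunit, with a ratio of 1.29 (1.26 to 1.32), and the pro-apoptotic Bax, with a ratio of 0.781 (0.668 to 0.912). The pore list lay at percentile 89.6. Mitochondrial calcium handling had a median of -0.05 (percentile 27.8), a sign that turned positive under the same scalings, with the carrier Slc25a23 at 2.64 against 4.15 FPKM. Calcein and dye handling had a median of 0.15 (percentile 99.6) but a mean of -0.05, and did not stand apart at a mean of at least 5 FPKM. In that list 8 of 13 genes had a positive difference short of 1.5-fold, while the iron exporter Slc40a1, at 5.87 against 12.6 FPKM, and the metal importer Slc39a8, at 0.924 against 1.93 FPKM, were lower by 1.5-fold or more.

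Among other mitochondrial lists, tricarboxylic acid cycle genes had a median of 0.15 (percentile 99.4, 21 of 23 positive, 0 by 1.5-fold), with Idh3a at 13.6 against 10.2 FPKM. Mitochondrial stress genes and chaperones had a median of 0.14 (percentile 98.7), with the serine synthesis enzyme Psat1 at 73.8 against 46.6 FPKM, and did not stand apart without Psat1. Mitochondrial ribosomal proteins had a median of 0.06 (percentile 99.6, 52 of 75 positive, 0 by 1.5-fold). Mitochondrially encoded genes had a median of -0.22 (percentile 0.525, 13 of 13 negative, 0 by 1.5-fold), with mt-Nd6 at 702 against 951 FPKM, and did not stand apart from random lists matched also on exon length. Among them mt-Co2, mt-Atp8, mt-Atp6 and mt-Nd3, at 13.4 FPKM or less in the low mPTP opening library, are uncertain, since reads of this stretch can be shared with a nuclear copy. Nuclear respiratory chain genes (median 0.02, percentile 45.6), dynamics and biogenesis (median 0.07, percentile 94.3) and glycolysis (median 0.01, percentile 46.1) did not stand apart.

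Histone lysine demethylases and methyltransferases, the enzymes that set histone methylation, did not stand apart. The demethylases had a median of -0.03 (percentile 41.9, 0 of 21 differing by 1.5-fold or more), a sign that turned positive after scaling by the trimmed mean or to a common sum. Kdm7a, with a ratio of 0.610 (0.532 to 0.699), was the furthest apart, and Kdm6b had a ratio of 0.883 (0.821 to 0.951). The methyltransferases had a median of 0.00 (percentile 76.2), with Ezh1 at 2.61 against 3.69 FPKM. Of 27 pluripotency genes 7 were measured, with a median of -0.26 (percentile 2.37), and these included Klf4, at 26.8 against 32.0 FPKM, and Klf2, at 22.8 against 32.4 FPKM. The others were Myc, Tbx3, Alpl, Tet1 and Tet2, and Klf4, Klf2 and Myc are also in the immediate early list. Nanog, Sox2, Lin28a, Esrrb and Zfp42 had a mean under 1 FPKM and were not measured, so the median says little about pluripotency. Among these, Sox2 was at 0.0594 against 1.00 FPKM (2 against 31 reads), 16.9-fold lower (4.29 to 145). The pluripotency list did not stand apart without its furthest member. Mesenchymal factors (median 0.03, percentile 59.2) did not stand apart, and 3 epithelial genes, Krt8, Krt18 and Krt19, had a median of -0.84. The epithelial median ran from -1.20 to -0.10 over the alternatives.

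Endoplasmic reticulum stress genes had a median of 0.20 (percentile 99.95, 0 of 21 by 1.5-fold), with the chaperone Hsp90b1 at 203 against 135 FPKM. Hypoxia response genes had a median of -0.15 (percentile 0.22), with Bnip3 at 6.34 against 10.9 FPKM, but did not stand apart at a mean of at least 5 FPKM. The metal response list, which bears on the cobalt in the assay, had a median of -0.20 (percentile 3.59) and did not stand apart. It did so at a mean of at least 5 FPKM (-0.49) or with a pseudocount of 5 FPKM (-0.19), while its median was -0.027 without its furthest member and without a filter. Hmox1, heme oxygenase, was 1.91-fold lower (1.80 to 2.02) and Mt1, a metallothionein, 1.74-fold lower (1.64 to 1.86). A link of these genes to the macrophage median of -0.94 was not tested. Antioxidant defence (median 0.06, mean -0.01, percentile 81.7) and heat shock (median -0.03, percentile 23.6, positive after scaling by the trimmed mean or to a common sum) did not stand apart. In all, 24 of 42 lists with a percentile lay outside the central 95% of random lists, 12 higher and 12 lower, against 2.1 by chance for independent lists, although these lists share genes. The 2.1 also takes genes within a list to vary independently, as in the random lists. Genes of a common function may vary together, so it is no measure of chance for these lists.

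**Figure D3:**
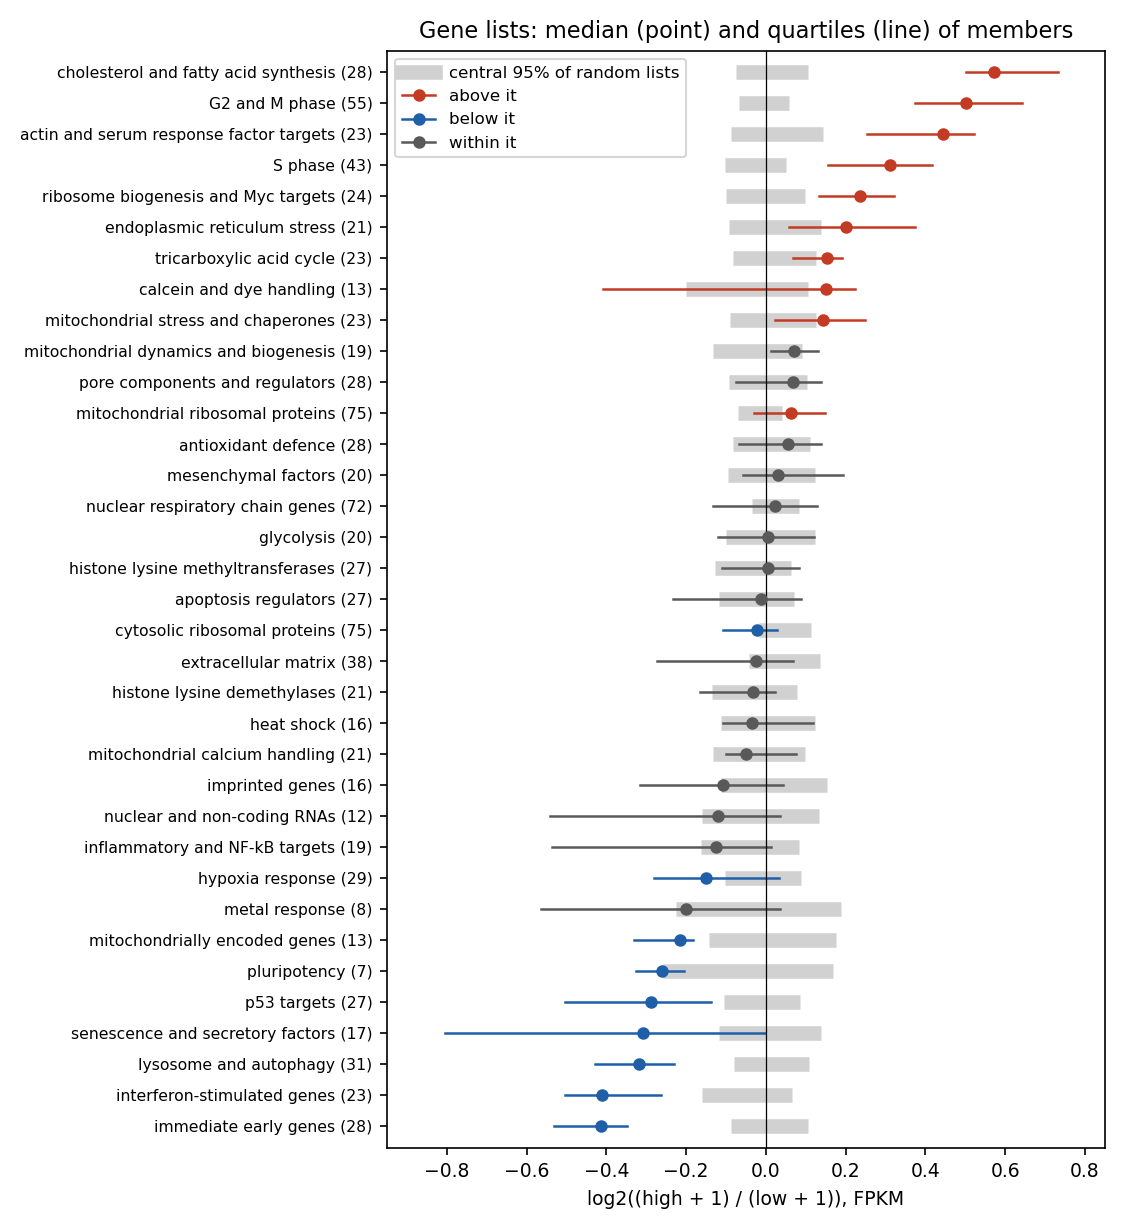
For each gene list (measured members in brackets), the point is the median and the line spans the quartiles of log2((high + 1)/(low + 1)) of FPKM, and the grey bar is the central 95% of medians of 10000 matched random lists. Cholesterol and fatty acid synthesis (0.57) and G2 and M phase (0.50) lie furthest to the right of their bars, and immediate early and interferon-stimulated genes (both -0.41) furthest to the left.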

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

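The random lists matched also on exon length and the counts without short genes were chosen after the data were seen. No leave-one-out or paired analysis was possible because each group had 1 library, and raw counts scaled by depth were not tried because the table holds FPKM only. Of the 24 lists that stood apart, 16 did so under every alternative that gave a value, 9 higher and 7 lower. Of the gene list values 414 of 442 were rated the same, and of the marker list values 103 of 114. For lists with a percentile this means that the call was kept. Lists without a percentile have no call, and for them it means only that the median moved little for a list of that size. Of the named genes, the 16 with the largest differences were recomputed, and none changed sign in 96 values, 24 of which moved beyond the counting interval. The number of genes past the size rule depended on the setting by construction. For higher and lower genes it was 75 and 276 with a pseudocount of 0.1 FPKM, 3 and 13 with 5 FPKM, 84 and 179 without a filter, 8 and 32 at a mean of at least 5 FPKM, 183 and 521 at 1.5-fold, 2 and 12 at 4-fold, 11 and 60 without predicted names, and 11 and 60 without genes under 600 nt of exon. Scaling to a sum of 1000000 gave 269 and 385, and 292 and 434 without mitochondrially encoded genes (40.2% higher), and it also multiplies all values, which changes the weight of the pseudocount and the filter.

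The cytosolic ribosomal protein median reversed to 0.059 with the trimmed mean, 0.10 with scaling to 1000000 and 0.10 without mitochondrially encoded genes, and at -0.022 with unmatched lists and -0.050 with length matching it no longer stood apart. The following medians no longer stood apart, and the cause was not tested. Pluripotency was at -0.14 with a pseudocount of 5 FPKM, -0.13 under both scalings to 1000000, -0.055 without a filter, -0.31 at a mean of at least 5 FPKM and -0.25 without its furthest member. Mitochondrial stress and chaperones was at 0.10 with a pseudocount of 5 FPKM and 0.12 without its furthest member, and mitochondrially encoded genes at -0.18 with length matching. At a mean of at least 5 FPKM, calcein and dye handling was at 0.17, hypoxia response at -0.036, chondrocyte markers at 0.11 and mesothelial markers at -1.17, the last with too few members for a percentile. Chondrocyte markers were also at 0.24 under both scalings to 1000000 and 0.043 without a filter. Lists that newly stood apart were metal response, at -0.19 with a pseudocount of 5 FPKM and -0.49 at a mean of at least 5 FPKM, and inflammatory targets, at -0.15 and -0.16 under the scalings to 1000000 and -0.17 without a filter. Imprinted genes did so at -0.11 with a pseudocount of 5 FPKM, -0.15 at a mean of at least 5 FPKM and -0.16 with length matching, and extracellular matrix at -0.078 with length matching. Among lists without a percentile, epithelial genes moved to -1.20 and -0.38 with pseudocounts of 0.1 and 5 FPKM and -0.10 without a filter, and keratinocyte markers to -0.41 with 5 FPKM and -0.19 without a filter. Skeletal muscle markers moved to -0.21 without a filter and 0.39 at a mean of at least 5 FPKM, cardiac markers to -0.20 without a filter and adipocyte markers to -0.43 with 5 FPKM. Among all measured genes counting error alone gave up to 36 higher genes past 2-fold, and up to 4 at a mean of at least 5 FPKM.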

Other observations

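Extracellular matrix genes went both ways. The list had a median of -0.03 (percentile 6.33), a sign that turned positive after scaling by a trimmed mean or to a common sum, with the small proteoglycan Lum at 91.6 against 147 FPKM, the fibrillar-associated collagen Col14a1 at 28.7 against 44.2 FPKM and the wound matrix gene Tnc at 245 against 156 FPKM in the high and low mPTP opening libraries. Imprinted genes had a median of -0.11 (percentile 3.01), which turned positive after scaling to a common sum, with the growth inhibitor Cdkn1c at 69.3 against 125 FPKM, 1.80-fold lower (1.71 to 1.90), Dlk1 at 90.2 against 137 FPKM and Peg10 at 12.9 against 9.39 FPKM. Nuclear and non-coding RNAs had a median of -0.12 (percentile 6.77), with Meg3 at 25.1 against 41.2 FPKM and Malat1 at 55.0 against 87.7 FPKM. Y-linked genes and Xist had a median of -0.10 over 4 genes, with Xist at 28.5 against 33.1 FPKM and Ddx3y at 10.8 against 10.6 FPKM. That median ran from -0.21 to 0.016 over the alternatives, so its sign is not settled.

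The transcript with the highest FPKM in both libraries was Gm23935, a small RNA of microRNA biotype, at 17132 against 39944 FPKM, which was 5.89% against 12.6% of all FPKM. Its rank comes from division by 57 nt of exon. Its recovered reads were 15991 against 34290, fewer than the 174145 against 169769 of mt-Co1. By FPKM, Gm23935 was followed by mt-Co1, at 6883 against 7296 FPKM, with Eef1a1, a translation elongation factor, at 3536 against 3495 FPKM and mt-Cytb at 3310 against 3761 FPKM as the third-ranked genes of the high and low libraries. In the mitochondrial genome, 6 of 13 coding genes, in the stretch from 7013 to 10173, were at 13.4 FPKM or less in the low and 11.9 or less in the high mPTP opening library, while the other genes were at 951 and 702 FPKM or more. This stretch was noticed after its values were seen. Its levels are uncertain, since the mouse nuclear genome holds a near-identical copy of much of it and the treatment of reads that map to both is not given in the sources used here.

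Of the tests that follow, those of chondrocyte markers and fibroblast markers and both tests of short transcripts were chosen after the results were seen. Of 16 macrophage markers 13 were 1.5-fold or more lower in the high mPTP opening library. A second list of 27 leukocyte genes, in none of the fixed lists of markers and written before its values were looked at, had a median of -0.66 (quartiles -0.82 and -0.58, 26 negative), which is in line with fewer macrophages in the dim pool, where the labels name no gate on leukocytes, with Mpeg1 at 23.5 against 41.8 FPKM and the most abundant macrophage marker, Lyz2, at 136 against 301 FPKM. A larger share of fibroblasts that lowers every other cell type alike goes with the mesothelial (-0.75), keratinocyte (-0.83, 4 genes), adipocyte (-0.74, 4 genes) and cardiac (-0.66, 2 genes) medians, of which the keratinocyte and cardiac ones were -0.19 and -0.20 without a filter. The keratinocyte genes were Krt8, Krt18, Perp and Krt19, which is also a mesothelial marker. Krt5, Krt14, Krt15 and Trp63 were under 1 FPKM in both libraries. The adipocyte genes were Cd36, Cebpa, Lpl and Pparg, and the cardiac genes Gata4 and Hand2. These medians are not shown to stand for separate cell types. A larger share of fibroblasts alone does not go with the far lower glial genes Sox10 (36.2-fold, 15.6 to 152) and Cdh19 (47.2-fold, 19.9 to 147). Chondrocyte markers were not lower as a list, with a median of 0.20 (positive under every alternative, standing apart in 5 of 9). Among them Col9a2 was 2.37-fold lower (1.86 to 3.04). Their lower quartile of 0.07 lay above the upper quartile of -0.60 of macrophage markers, the bound set against this explanation. However, this test was chosen after the median was seen. Its genes are not shown to be limited to chondrocytes, so it cannot decide. The skeletal muscle (-0.53, 2 of 4 lower, Des 2.16-fold higher), smooth muscle (0.18), neuronal (-0.04), endothelial (-0.03) and osteoblast (-0.07) medians cannot decide either. Their measured genes are not shown to be limited to these cell types. Some are also in the actin list or, as Col1a1, among the fibroblast markers. Under a mean of 1 FPKM, Tek was 2.94-fold lower (1.82 to 4.92) but Emcn 4.90-fold higher (2.38 to 11.4). Dcx there was 3.13-fold lower (1.74 to 5.92) and Elavl4 had a ratio of 1.49 (0.772 to 2.98). The sort itself, if macrophages keep or take up more calcein than fibroblasts, stays open and was not tested, as does lower expression of the macrophage markers in the same number of macrophages.

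The medians of the cell cycle lists were higher in the high mPTP opening library, with 20 of 55 G2 and M phase genes and 1 of 43 S phase genes past 1.5-fold. Exon length is argued against by the G2 and M phase median, which was 0.50 after the median of genes of like level and length was subtracted. Dilution by fewer macrophages would raise fibroblast markers as well, but their upper quartile of 0.067 lay below the lower quartile of 0.37 of the G2 and M phase genes. A difference in the share of cycling cells between the pools, or in sorting or culture, was not tested and stays open.

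Short transcripts scattered both ways, with a median of -0.32 over 209 measured genes under 200 nt (quartiles -0.89 and 0.44), and without genes under 600 nt the genes past 2-fold went from 39 to 11 higher and from 114 to 60 lower. Over 75 cytosolic ribosomal protein genes, whose median was -0.02 (percentile 1.61) and turned positive after scaling by a trimmed mean or to a common sum, the difference and exon length had a rank correlation of 0.31, against 0.04 over 11127 protein-coding genes. The shortest, such as Rpl39, at 81.8 against 134 FPKM, had prompted the test. Protein-coding genes under 600 nt lay -0.096 from the median of all protein-coding genes, or -0.088 without ribosomal protein genes, between the bounds set for a trend with exon length and for a loss of small RNAs alone, so these cannot be told apart with the 47 short genes measured. No biological explanation was tested.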
